A study of Mus musculus with 18 samples.

How the data were processed

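Liver RNA of offspring of the outbred mouse line DUK was measured on 18 Affymetrix Mouse Genome 430 2.0 arrays, in 6 groups of 3 arrays. Dams received isoenergetic diets with 20% (control) or 40% (high protein, HP) protein by weight; HP was given in pregnancy or in lactation, and livers were taken at postnatal day 21 or 150. Per the labels each array carried biotin-labelled cRNA from a pool of livers. The labels disagree on how many animals entered a pool, and it is unclear whether pools of a group share animals. The p-values therefore describe the spread between pools, not between animals or dams, and are too small if pools share animals. The HP lactation arrays of day 150 are numbered 4 to 6 and all others 1 to 3; the labels name no pairing, so the numbers were not used as a block in the main tests. Sex, scan date and detection calls were not given.

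The values are array signal intensities deposited by the authors, made with MAS5 in GCOS 1.4 per the labels, on a linear scale on which the trimmed mean of each array lay between 499.8 and 501.5. No further scaling was applied. The log2 of the signal was taken with 0 added. Mean signals of a gene in a group are geometric means throughout, that is, means of the log2 signal turned back to the linear scale. Of 45101 probe sets, 64 were controls; 34958 named 1 gene symbol, 932 several and 9211 none, and 34754 of the first were matched to the reference annotation by gene ID. Probe sets with a mean log2 signal at or above the median of the non-control sets (5.85, a signal of 57.5) were kept (22519, of which 19349 name 1 gene). For genes with several kept probe sets the one with the highest mean signal was used, which left 11018 genes. Probe sets with several or no symbols were left out, as were those under the filter. The precision is set by the 3 arrays per group: the median standard error of a log2 change was 0.189 for a difference of 2 groups and 0.267 for a difference of differences, with 12 residual degrees of freedom plus 6.47 from the shared prior.

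Group means were fitted in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit, eBayes with trend) over all 18 arrays, with Benjamini-Hochberg adjustment in each comparison and a threshold of 0.05, for 9 comparisons: each HP group against control of the same day, the HP groups against each other at each day, day 150 against day 21 in control, and the difference of diet responses between days for each diet. All tests were two-sided. Of 46 gene lists, 43 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01 in the comparisons with control and with age, beside camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. Overlap of the diet responses was set beside 1000 simulations in which the residuals were rotated at random to make unchanged groups that share controls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

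The groups, comparisons, tests, gene lists, probe set choice, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named, per comparison with control and for age, up to 10 rising and 10 falling genes with the largest changes among those past the threshold whose 3 values in one group lie beyond the 3 of the other, filled up with the smallest p where fewer passed, and up to 4 members of each list with the smallest p; for the other comparisons, up to 3 in each direction. Dnmt1, Dnmt3a, Dnmt3b, Igf1, Cyp7a1, Pck1, Cps1 and Asns could always be named. The text names a subset of the genes that the rule allows. Alternatives were no filter, a filter at the 70th percentile, quantile normalization, equal 75th percentiles, 50 added to the signal, every kept probe set, eBayes without trend, array weights, an adjusted p under 0.10, the compared arrays alone, a replicate block, and each array left out; a fit without the arrays with Xist signal and one with the 3'/5' control ratios as a covariate were added later.

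The code was tested on simulated data with the means and spreads of the 11018 genes, in 10 simulations of 200 changed genes each for HP pregnancy against control at day 150. It recovered 19% (95 of 500) of changes of 0.5 on the log2 scale, 65.8% of changes of 1, 83.2% of 1.5 and 91.4% of 2, with 75 false calls among 1395 (5.38%) and 0 calls in a comparison without changes. Camera found a list shifted by 0.5 in 10 of 10 simulations and called 2 other lists in all. The simulated genes varied independently of each other, so this does not show how often camera calls lists falsely in the real arrays. There, splits that mix the groups gave up to 21 lists.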

Results

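The comparisons addressed how the liver transcripts of mouse offspring differed when their dams ate a high protein (HP) diet of 40% in pregnancy alone or in lactation alone, against 20% throughout. The arrays parted first by day. The first principal component (43.4% of the variance) put the day 21 arrays on one side and the day 150 arrays on the other. The median correlation between arrays was 0.976 within groups, 0.973 between groups of one day and 0.942 between days. Of 11018 genes tested, 1959 differed between day 150 and day 21 in control offspring. Against control of the same day, 19 genes differed after HP lactation at day 21, 290 after HP pregnancy at day 150, 1 after HP lactation at day 150 and 0 after HP pregnancy at day 21. Each array held RNA pooled from several livers, so every standard error below describes the spread between pools. It was estimated over all 6 groups of 3 arrays together, not from the compared groups alone. Xist, the transcript of the inactive X chromosome, had a signal of 2026 in control day 21 replicate 2 and 5080 in HP lactation day 150 replicate 4 on 1 of its probe sets, and at most 35.3 in the other arrays. On the other Xist probe set these signals were 7343, 11644 and at most 93.

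**Figure D1:**
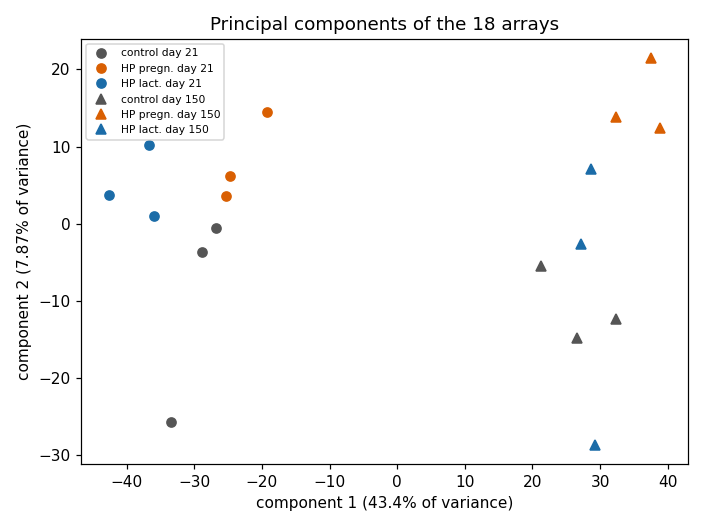
Principal components of the 18 arrays over the tested genes: component 1 (43.4% of the variance) against component 2 (7.87%), 1 point per array, coloured by maternal diet, with circles for day 21 and triangles for day 150. Day 21 and day 150 lie apart on component 1.

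After HP feeding in lactation, genes typical of the male liver were lower at day 21. Mup3, a major urinary protein, had a mean signal of 2676 against 22030 in control (log2 change -3.04, SE 0.29, adjusted p = 4.4e-05). Elovl3, a fatty acid elongase, had 61.8 against 369.8 (log2 change -2.58, SE 0.41, adjusted p = 0.0094). Slco1a1, an organic anion uptake transporter, had 6049.7 against 12065 (log2 change -0.996, SE 0.14, adjusted p = 0.0035). In each of these genes the 3 HP lactation arrays lay below the 3 control arrays. The rule for naming genes by the size of their change asked for such a separation, so it is no further support. Among genes not so chosen, chance gives it in 10% when either order counts. The Mup3 probe set can bind transcripts of related Mup genes. Of the 19 male-biased genes measured, 3 fell and 0 rose. Adjusted over the list alone, 10 fell. The list's median log2 change was -0.52, with 17 of 19 changes negative (camera adjusted p = 1.7e-11, adjusted p = 0.090 with an estimated correlation).

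**Figure D2:**
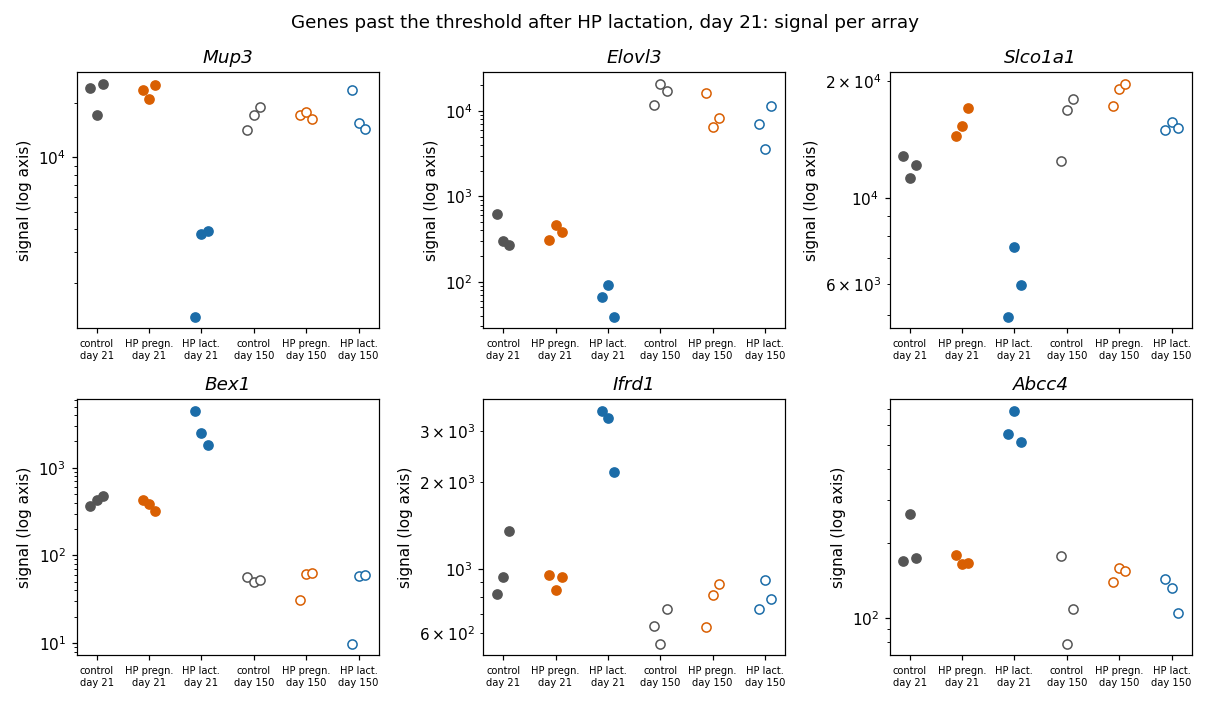
Signal (log axis) of 6 genes past the threshold after HP lactation at day 21, 1 point per array and 3 arrays per group, with filled points for day 21 and open points for day 150. The 3 HP lactation day 21 arrays lie outside the range of the other day 21 arrays in each gene.

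Other genes that fell at day 21 after HP lactation were Rab32, a small GTPase (log2 change -1.06, SE 0.14), Ces1f, a carboxylesterase (-1.02, SE 0.15), and Mme, the peptidase neprilysin (-1.27, SE 0.25). Lower too were Rad51b and Rdm1, of homologous recombination (-1.34, SE 0.25, and -0.996, SE 0.17). Those that rose were Bex1, of the fetal and imprinted list (2.69, SE 0.50), Abcc4, an efflux transporter (1.55, SE 0.25), and Ifrd1, a transcriptional coregulator (1.54, SE 0.20). Smaller rises were those of Ppat, the first committed enzyme of purine synthesis (0.94, SE 0.19), and of Acsl4, an acyl-CoA synthetase (0.86, SE 0.14). All 14 falling and 5 rising genes make up the count of 19, of which 10 changed more than 2-fold. The excess of falling genes depended on the processing: 33 rose and 20 fell with every kept probe set, 5 and 3 with the compared arrays alone, and 51 and 28 without HP lactation day 21 replicate 3. In all of the genes named here the 3 arrays of one group lay beyond the 3 of the other.

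Several gene lists passed camera at the preset correlation in the same comparison, while fry called 3, the male-biased, fetal and clock lists. Of 18 fetal liver and imprinted growth genes 1 rose (Bex1), 5 rose when adjusted over the list alone, and 16 were positive (median 0.55, camera adjusted p = 3.6e-05, adjusted p = 0.090 with an estimated correlation). Grb10 and Peg3, both imprinted, had log2 changes of 0.90 (SE 0.25) and 0.85 (SE 0.28) that did not pass, and Peg3 was at 0.42 without HP lactation day 21 replicate 1. Of 18 clock genes 0 passed and 6 rose when adjusted over the list alone (median 0.56, camera adjusted p = 3.5e-05, adjusted p = 0.090 with an estimated correlation). Per3 was at 2.11 (SE 0.56) and Cry2 at 0.96 (SE 0.29). All 9 clock genes that peak late in the light phase or at dusk were positive, with a median of 1.09 against -0.23 in 5 genes in antiphase, and no sampling time is given. After HP pregnancy at day 21 these medians were -0.19 and 0.17. Of 27 cell cycle genes 0 passed, 1 rose when adjusted over the list alone and 25 were positive (median 0.57, camera adjusted p = 2.2e-05, adjusted p = 0.41 with an estimated correlation). Ccne2 was at 1.26 (SE 0.35). This list no longer passed without HP lactation day 21 replicate 3 (median 0.15, adjusted p = 0.25).

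Of 21 cholesterol synthesis genes 0 passed, 6 rose when adjusted over the list alone and 19 were positive (median 0.50, camera adjusted p = 3.5e-05, adjusted p = 0.45 with an estimated correlation). Examples were Idi1 at 0.84 (SE 0.24), Lss at 0.93 (SE 0.28) and Sqle, squalene epoxidase, at 1.07 (SE 0.34), none of which passed over all genes. Without control day 21 replicate 3 the list had a median of 0.29 (adjusted p = 0.080). Of 31 complement and coagulation genes 0 passed, 7 fell when adjusted over the list alone and 29 were negative (median -0.27, camera adjusted p = 4.2e-10, adjusted p = 0.35 with an estimated correlation). Proc, the protein C precursor, had a log2 change of -0.51 (SE 0.11, adjusted p = 0.060). It passed without control day 21 replicate 3 (-0.59, adjusted p = 0.024) or HP lactation day 21 replicate 2 (-0.60, adjusted p = 0.022). Of 68 oxidative phosphorylation genes 0 passed and 67 were negative (median -0.26, camera adjusted p = 3.1e-18, adjusted p = 0.39 with an estimated correlation). The HP lactation arrays of day 21 also had a narrower signal range, with a mean 99th percentile of 16150 (SD 1430.1) against 18781 (SD 1102) in control. Their top decile of signal had a median log2 change of -0.21. After quantile normalization the oxidative phosphorylation list no longer passed (median -0.05, adjusted p = 0.17), while the male-biased, fetal, clock, cell cycle, cholesterol and complement lists still did.

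Of the liver's growth hormone and steroid genes, Igf1 had a log2 change of -0.47 (SE 0.13, adjusted p = 0.15), Sult3a1, a female-biased sulfotransferase, -2.54 (SE 0.73), and Cyp3a16, a female-biased cytochrome P450, 3.20 (SE 0.86). None of these passed. The 22 female-biased genes had a median of 0.41 that passed only after quantile normalization (0.38, adjusted p = 0.025) and was 0.25 without control day 21 replicate 2, the control array with Xist signal. Dnmt3a, a DNA methyltransferase, was at 0.51 (SE 0.22, adjusted p = 0.31), with the opposite sign in 1 of its 3 other kept probe sets. In limma, 1578 genes had an unadjusted p under 0.05, against 550.9 by chance. The count of 19 became 6, 10 and 63 without control day 21 replicates 1, 2 and 3. It became 10, 57 and 79 without HP lactation day 21 replicates 1, 2 and 3. Mup3, Slco1a1, Ces1f, Rab32 and Ifrd1 passed each time. With the compared arrays alone Mup3 was the only one of these to pass (adjusted p = 0.018, and 0.053 to 0.10 for the others), and 4 of the 19 genes did, against 7 of 19 with the 3'/5' ratios as a covariate. At day 21 the mean Gapdh 3'/5' ratio was 0.843 (SD 0.027) after HP lactation and 0.942 (SD 0.085) in control. Elovl3 and Abcc4 missed without control day 21 replicate 1 (adjusted p = 0.076 for each).

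After HP feeding in pregnancy, no gene passed at day 21 (0 of 11018 in limma; 1100 at an unadjusted p under 0.05 against 550.9 by chance). The smallest adjusted p was 0.071, for Carmil2, a regulator of the actin cytoskeleton (log2 change 1.05, SE 0.17). Carmil2 passed in limma without trend (adjusted p = 0.017) and with array weights (1.08, adjusted p = 0.0071). Without control day 21 replicate 3, 1 gene passed: Malt1, of lymphocyte signalling (1.75, adjusted p = 0.025), named after its value had been seen. Hsd3b5, a male-biased steroid dehydrogenase, had a mean signal of 1744 against 496.7 in control (1.81, SE 0.42, adjusted p = 0.27). Itgav, an integrin, had a log2 change of 0.77 (SE 0.17, adjusted p = 0.26), Slc4a4, a bicarbonate transporter, 0.58 (SE 0.13, adjusted p = 0.26) and Agt, angiotensinogen, -0.48 (SE 0.13, adjusted p = 0.28). The 3 arrays of one group lay beyond the 3 of the other in each of these genes. Igf1 was at -0.13 (SE 0.13), a sign that quantile normalization turned (0.02) and that its 3 other kept probe sets did not share. Pck1, of gluconeogenesis, was at -0.55 (SE 0.19), and Dnmt3a at 0.43 (SE 0.22). Of the other kept probe sets, 1 of 2 for Pck1 and 1 of 3 for Dnmt3a had the opposite sign.

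Among the lists at day 21 after HP pregnancy, 3 of the 20 that passed also did so after quantile normalization. Macrophage genes were higher (22 measured, 0 passed, 20 positive, median 0.22, camera adjusted p = 0.00045, adjusted p = 0.45 with an estimated correlation). Without control day 21 replicate 3 the median was 0.14. Mpeg1, a pore-forming protein of macrophages, was at 0.54 (SE 0.17) and Timd4, a receptor of resident macrophages, at 0.60 (SE 0.23). Proteasome genes were lower (31 measured, 0 passed, 27 negative, median -0.20, camera adjusted p = 3.2e-08, adjusted p = 0.30 with an estimated correlation). Psmc3 was at -0.39 (SE 0.11) and Psmd13 at -0.52 (SE 0.16), and 1 of the 3 other kept probe sets of Psmd13 had the opposite sign. Glucocorticoid and fasting genes were lower (23 measured, 0 passed, 22 negative, median -0.30, camera adjusted p = 0.00011, adjusted p = 0.45 with an estimated correlation). Lpin1 was at -1.04 (SE 0.45) and Tat, tyrosine aminotransferase, at -0.64 (SE 0.30). Without HP pregnancy day 21 replicate 3 this list did not pass (median -0.18, adjusted p = 0.067), and without replicate 1 its median was -0.54. Single arrays moved Lpin1 from -1.59 to -0.70 and Tat from -0.99 to -0.41.

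Oxidative phosphorylation (median -0.20, 65 of 68 negative), cytosolic ribosomal proteins (-0.26, 40 of 42), amino acid catabolism (-0.19, 31 of 39), the urea cycle (-0.21, 13 of 13) and methionine and one-carbon metabolism (-0.23, 12 of 15) passed on the deposited scale, each with 0 genes past the threshold. Their adjusted p with an estimated correlation lay between 0.30 and 0.35. None passed after quantile normalization, where the medians lay between -0.08 and -0.02. The HP pregnancy arrays of day 21 had a mean 99th percentile of 16547 (SD 734.3) against 18781 (SD 1102) in control. The male-biased list passed only after quantile normalization (median 0.17, adjusted p = 0.0095), or without control day 21 replicate 1 (0.30, adjusted p = 0.015) or HP pregnancy day 21 replicate 1 (0.23, adjusted p = 0.018). On the deposited scale it was at 0.20, with 14 of 19 positive, and at 0.07 without control day 21 replicate 3.

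**Figure D3:**
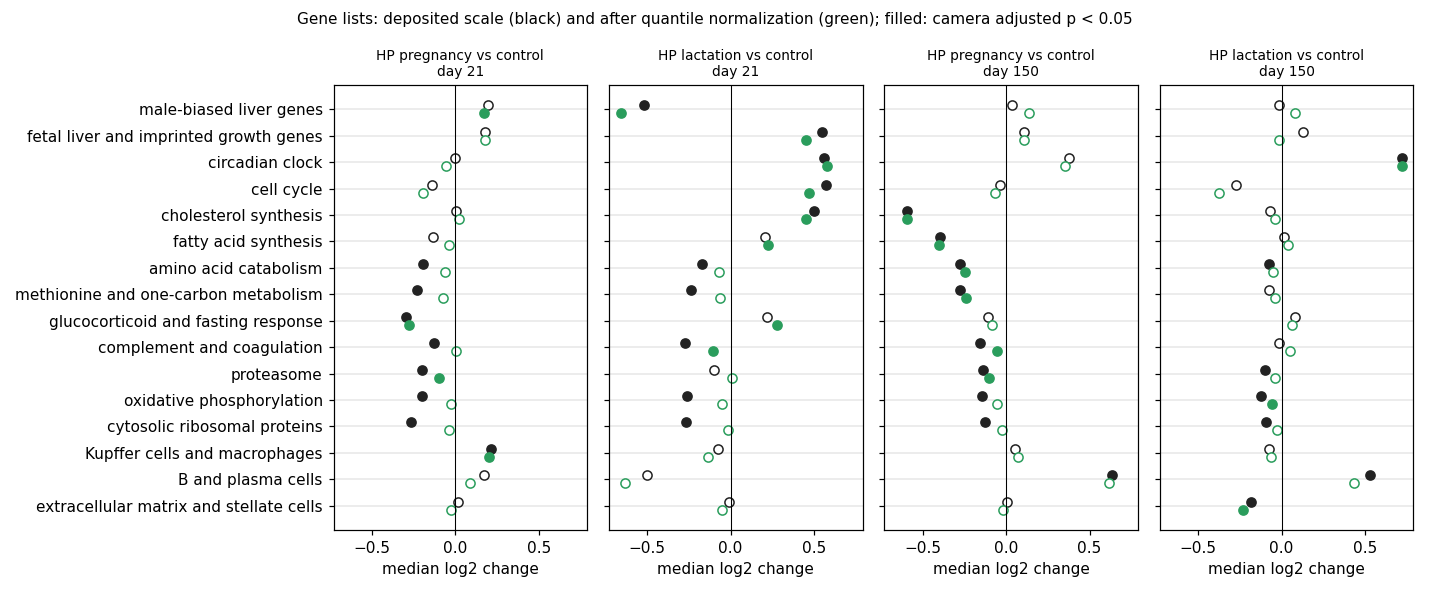
Median log2 change of the members of 16 gene lists in each HP group against control, on the deposited scale (black) and after quantile normalization (green); filled points passed camera at the preset correlation. At day 21 the lists of abundant transcripts, such as cytosolic ribosomal proteins, lie below 0 on the deposited scale and near 0 after quantile normalization, while male-biased genes after HP lactation lie below 0 on both.

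Set against each other at day 21, the HP groups differed in 141 genes, 99 higher and 42 lower after HP pregnancy than after HP lactation. Of these, 59 differed more than 2-fold. Hsd3b5 was higher by 3.57 on the log2 scale (SE 0.42, adjusted p = 0.00024; signals 1744 and 146.4), Mup3 by 3.12 (SE 0.29, adjusted p = 2.9e-05) and Elovl3 by 2.61 (SE 0.41, adjusted p = 0.0033). Sult1e1, the estrogen sulfotransferase, was lower (-5.31, SE 0.96, adjusted p = 0.010; signals 99.7 and 3945). So were Cyp3a16 (-3.90, SE 0.86, adjusted p = 0.030) and Cyp26a1, which clears retinoic acid (-2.93, SE 0.69, adjusted p = 0.042). The 3 arrays of one group lay beyond the 3 of the other in each of these genes. Cyp26a1 had signals of 78.8, 7.5 and 68.9 after HP pregnancy, near background, so that the size of its difference is imprecise. Without 1 array the count ran from 33 (without HP pregnancy day 21 replicate 2 or 3, or HP lactation day 21 replicate 1) through 67 (HP pregnancy day 21 replicate 1) to 361 (HP lactation day 21 replicate 3). Hsd3b5, Mup3 and Elovl3 were past the threshold each time. Sult1e1, Cyp3a16 and Cyp26a1 missed it in 2, 5 and 4 of the 6 leave-outs, with adjusted p up to 0.059, 0.14 and 0.26.

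Across genes, the changes from control after HP pregnancy and after HP lactation correlated at day 21 with r = 0.31 (covariance 0.031). Genes are not independent replicates, and both changes share the 3 control arrays, which alone gives a mean r of 0.50 (covariance 0.039) in 1000 simulations of unchanged groups. The observed r lay below the simulated range of r, 0.36 to 0.63, and ran from 0.20 to 0.49 as single arrays were left out. The covariance differed from the simulated mean by -0.0077 and lay within the simulated range of 0.025 to 0.055. With 0 genes past the threshold after HP pregnancy, the overlap of passing genes was 0.

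At day 150, long after exposure, the genes that fell after HP pregnancy included some of cholesterol synthesis and amino acid breakdown. As lists these passed camera at the preset correlation but not with an estimated one, and fry called 0 lists in this comparison. Fdps, farnesyl diphosphate synthase, had a mean signal of 2577 against 5207 in control (log2 change -1.02, SE 0.26, adjusted p = 0.043). Ebp, a sterol isomerase, was at -0.50 (SE 0.12, adjusted p = 0.038) and Rdh11, a retinol dehydrogenase, -0.97 (SE 0.23, adjusted p = 0.038). Of 21 cholesterol synthesis genes 3 fell and 0 rose. Adjusted over the list alone, 11 fell (median -0.59, 17 negative, camera adjusted p = 2.1e-06, adjusted p = 0.62 with an estimated correlation). Of 39 amino acid catabolism genes 2 fell, 3 when adjusted over the list alone, and 34 were negative (median -0.28, camera adjusted p = 2.1e-06, adjusted p = 0.54 with an estimated correlation). They were Pcca, of propionate breakdown (-0.60, SE 0.12), and Gcdh, of lysine breakdown (-0.47, SE 0.12). Of 15 methionine and one-carbon genes 2 fell, 3 when adjusted over the list alone (median -0.28, camera adjusted p = 0.00025, adjusted p = 0.54 with an estimated correlation): Sardh, sarcosine dehydrogenase (-0.49, SE 0.12), and Aldh7a1, an aldehyde dehydrogenase (-0.50, SE 0.12). In each gene named the 3 HP pregnancy arrays lay below the 3 control arrays.

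**Figure D4:**
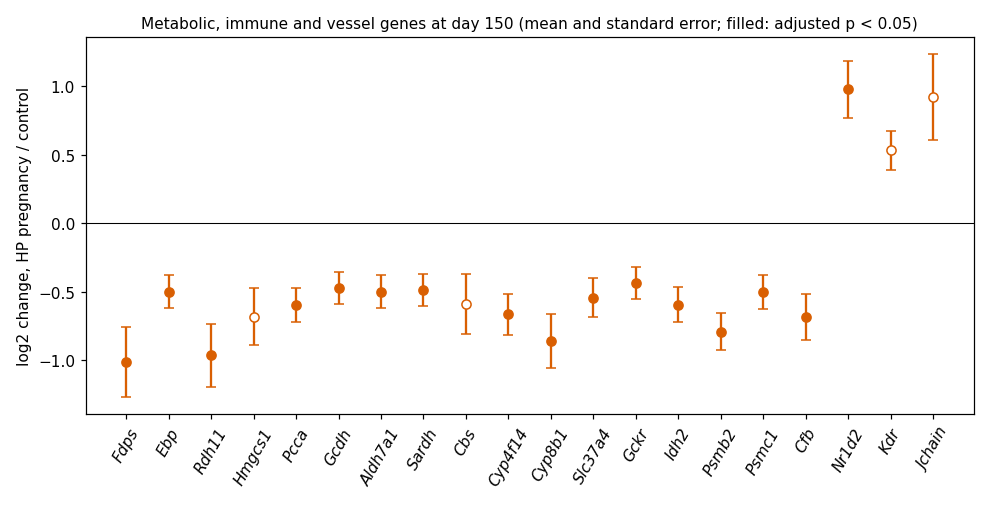
Log2 change of 20 genes after HP pregnancy against control at day 150: points are differences of group means (3 arrays per group), bars are standard errors, and filled points have an adjusted p under 0.05. Genes of cholesterol, amino acid and glucose metabolism lie below 0, while Nr1d2, Kdr and Jchain lie above.

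Further metabolic genes that fell were Slc37a4, the glucose phosphate transporter of the endoplasmic reticulum (-0.54, SE 0.14), Gckr, the glucokinase regulator (-0.44, SE 0.12), Idh2, mitochondrial isocitrate dehydrogenase (-0.59, SE 0.13), and Cyp8b1, of bile acid synthesis (-0.86, SE 0.20). Lower too were Cyp4f14, a fatty acid hydroxylase (-0.67, SE 0.15), Mogat1, a monoacylglycerol acyltransferase (-1.84, SE 0.37), and Aqp8, a water channel (-1.14, SE 0.28). Mogat1 had signals of 39.3, 27.9 and 58 after HP pregnancy, near background, so that the size of its fall is imprecise. Cyp4a14, a PPAR alpha target, was at 7300 against 21031 (-1.53, SE 0.41, adjusted p = 0.056). Phase I drug metabolism was lower (34 measured, 1 fell, 5 when adjusted over the list alone, median -0.26, camera adjusted p = 0.00019, adjusted p = 0.54 with an estimated correlation). So were fatty acid synthesis (22 measured, 0 passed, 2 when adjusted over the list alone, median -0.40, camera adjusted p = 0.00037, adjusted p = 0.62 with an estimated correlation) and fatty acid oxidation (32 measured, 0 passed, 7 when adjusted over the list alone, median -0.16, camera adjusted p = 0.0011, adjusted p = 0.63 with an estimated correlation). Psmb2 and Psmc1, of the proteasome, fell (-0.79, SE 0.14, and -0.50, SE 0.12), as did Cfb, complement factor B (-0.68, SE 0.17). Adjusted over the list alone, 4 of 31 proteasome and 10 of 31 complement and coagulation genes fell (medians -0.14 and -0.16, camera adjusted p = 0.0036 and 0.00024, adjusted p = 0.65 and 0.62 with an estimated correlation). These lists passed after quantile normalization as well, whereas oxidative phosphorylation (median -0.14, 55 of 68 negative, adjusted p = 0.65 with an estimated correlation) did not (median -0.05). The fatty acid oxidation list did not pass without HP pregnancy day 150 replicate 1 (adjusted p = 0.061).

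Genes that rose at day 150 after HP pregnancy included Nr1d2, a nuclear receptor of the clock (0.98, SE 0.21, adjusted p = 0.029), Fgfr1, a growth factor receptor (1.59, SE 0.37), Gdpd5, a phosphodiesterase (1.44, SE 0.35), Bend3 (1.08, SE 0.17) and Rpl39, a ribosomal protein (1.22, SE 0.30). The rise of Fgfr1 rests on 1 probe set, as its 2 others, under the filter, were at 0.39 (SE 0.54) and -0.76 (SE 0.88). Mycn, a transcription factor, was at a signal of 77.4 against 6.87 (3.49, SE 0.47, adjusted p = 0.0031), near background. The 2 further Mycn probe sets, under the filter, were at 0.56 (SE 1.13) and -1.06 (SE 0.63). Tmie, of the inner ear's transduction channel, fell from 202.9 to 13.97 (-3.86, SE 0.46, adjusted p = 0.0012) and Rassf4, a Ras-association protein, from 771.4 to 259.2 (-1.57, SE 0.25, adjusted p = 0.013). Endothelial genes (median 0.20, 15 of 22 positive, adjusted p = 0.65 with an estimated correlation), with Kdr, a vessel growth factor receptor, at 0.53 (SE 0.14), and B and plasma cell genes (median 0.64, 7 of 8 positive, adjusted p = 0.54 with an estimated correlation), with Jchain at 0.92 (SE 0.31), passed on the deposited scale only, with 0 genes past the threshold. The endothelial list did not pass without control day 150 replicate 1 or HP pregnancy day 150 replicate 2 (adjusted p up to 0.25). The B cell list did not pass without control day 150 replicate 1 or HP pregnancy day 150 replicate 3 (up to 0.12).

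In all, 168 genes rose and 122 fell after HP pregnancy at day 150, 25 of them more than 2-fold, with 2208 at an unadjusted p under 0.05 against 550.9 by chance. The balance depended on the scaling: with equal 75th percentiles 142 rose and 57 fell. Leaving out control day 150 replicates 1, 2 and 3 left 9, 35 and 47 genes, and leaving out HP pregnancy day 150 replicates 1, 2 and 3 left 162, 2 and 47. Mycn and Tmie passed each time, and each other gene named as risen or fallen missed the threshold at least once. The HP pregnancy arrays had a higher ratio of the 3'/5' probe sets of Gapdh, a measure of RNA integrity (mean 1.75, SD 0.072, against 1.48, SD 0.27, in control). With this ratio and that of beta-actin as a covariate 3 genes passed. The median change of the 290 genes was then 0.60 against 0.63 before, and their median SE 0.17 against 0.15.

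After HP lactation, only Mycn passed at day 150 in limma (signal 83.0 against 6.87; 3.59, SE 0.47, adjusted p = 0.0041), with 851 genes at an unadjusted p under 0.05 against 550.9 by chance. Mycn did not pass with 50 added to the signal before the log2 or with the compared arrays alone, and the stricter filter left it untested. Of 18 clock genes measured 0 passed over all genes. Adjusted over the list alone, 10 rose and 4 fell (median 0.72, camera adjusted p = 0.0052, adjusted p = 0.69 with an estimated correlation). Per2 had a mean signal of 380.1 against 134.2 in control, and Hlf was at 1.16 (SE 0.30) and Bhlhe40 at 0.96 (SE 0.26), while Cry1, a repressor of the clock, was at -0.95 (SE 0.23). The 3 arrays of one group lay beyond the 3 of the other in each. Other values that did not pass were Cyp4a14 at -1.54 (SE 0.41), Elovl3 at -1.30 (SE 0.41) and Slc37a4 at 0.51 (SE 0.14). Elovl3 is male-biased, and HP lactation day 150 replicate 4 had Xist signal, so female RNA in that pool was not told apart from the diet. Clpx, a mitochondrial protease component, was at -0.85 (SE 0.18), a sign that its other kept probe set did not share. Asns, asparagine synthetase, had a mean signal of 373.1 against 186.4, and neither of these genes passed. Cxcl9, an interferon-induced chemokine, was at -2.21 (SE 0.55) and passed without control day 150 replicate 2 (-3.12, adjusted p = 0.0038). Fgfr1, at 1.70 (SE 0.37), passed without control day 150 replicate 3 (2.16, adjusted p = 0.048), though its 2 other probe sets, under the filter, were at 0.31 (SE 0.54) and -0.56 (SE 0.88) with all arrays.

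Extracellular matrix genes were lower at day 150 after HP lactation (31 measured, 0 passed, 27 negative, median -0.18, camera adjusted p = 0.019, adjusted p = 0.85 with an estimated correlation), with Col3a1 at -0.88 (SE 0.34). The list did not pass without control day 150 replicate 3 (median -0.03, adjusted p = 0.99), HP lactation day 150 replicate 4 (-0.14, adjusted p = 0.078) or 6 (-0.16, adjusted p = 0.13). Oxidative phosphorylation genes were lower (median -0.12, 60 of 68 negative, 0 passed, camera adjusted p = 1.5e-08, adjusted p = 0.85 with an estimated correlation). B and plasma cell genes were higher (median 0.53, 8 of 8 positive, 0 passed, camera adjusted p = 0.021, adjusted p = 0.69 with an estimated correlation). They did not pass after quantile normalization (median 0.43, adjusted p = 0.056), nor without control day 150 replicate 1 (0.28, adjusted p = 0.13), HP lactation day 150 replicate 4 (0.40, adjusted p = 0.086) or 5 (0.37, adjusted p = 0.080). The HP lactation arrays of day 150 had a mean Gapdh 3'/5' ratio of 1.68 (SD 0.11) against 1.48 (SD 0.27) in control. The count of 1 gene became 3, 2 and 2 without control day 150 replicates 1, 2 and 3, and 3 without HP lactation day 150 replicate 6, with Mycn in each.

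The HP groups differed from each other at day 150 in 79 genes, 30 higher and 49 lower after HP pregnancy than after HP lactation, 8 of them more than 2-fold. The excess of lower genes depended on the processing: it was 60 higher and 25 lower with equal 75th percentiles, 65 and 65 with the stricter filter, and 62 and 64 with array weights. Tasor, of heterochromatin silencing, was higher (1.02, SE 0.19, adjusted p = 0.031), as was Gpatch2l (0.95, SE 0.20, adjusted p = 0.038). Tmie (-3.07, SE 0.46, adjusted p = 0.0097), Ctdspl, a phosphatase (-1.19, SE 0.19, adjusted p = 0.017), and Lss, lanosterol synthase (-1.29, SE 0.28, adjusted p = 0.044; signals 490.7 and 1197), were lower. In each the 3 arrays of one group lay beyond the 3 of the other. The count was 22, 3 and 2 without HP pregnancy day 150 replicates 1, 2 and 3, and 3, 251 and 2 without HP lactation day 150 replicates 4, 5 and 6. Of these arrays, HP lactation day 150 replicate 4 had Xist signal. Slc37a4 and Fads6 were the 2 genes that passed each time, both named here after their values had been seen. Each of the other genes named here missed the threshold in at least 3 of the 6 leave-outs.

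At day 150 the changes from control in both HP groups correlated across genes with r = 0.49 (covariance 0.057), beside a mean r of 0.50 (covariance 0.039, range 0.025 to 0.055) from shared controls alone in 1000 simulations. The covariance exceeded the simulated mean by 0.017, and part of the excess may come from the shared controls. It lay just above the simulated range, while r lay within the simulated range of r, 0.36 to 0.63. Mycn rose in both groups and 0 genes fell in both. Both Mycn calls rest on the same 3 control arrays, with signals of 4.3, 5.8 and 13 near background, so they are not independent of each other.

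In control offspring far more genes differed between day 150 and day 21 than between either HP group and control. Elovl3 rose from 369.8 to 16193 (log2 change 5.45, SE 0.41, adjusted p = 1.2e-07), Cyp7b1, an oxysterol hydroxylase, from 1226 to 25850 (4.40, SE 0.16, adjusted p = 2.0e-12). Hsd3b5 and Cyp4a12a, both male-biased, rose by 4.34 (SE 0.42) and 4.13 (SE 0.31). Of 19 male-biased genes 13 rose and 0 fell (16 rose when adjusted over the list alone, median 1.39, camera adjusted p = 1.7e-15, adjusted p = 0.029 with an estimated correlation). Of 22 female-biased genes 13 fell and 1 rose (14 and 1 when adjusted over the list alone, median -2.08, camera adjusted p = 4.9e-08, adjusted p = 0.063 with an estimated correlation). Sult2a2, a sulfotransferase, was at 20.1 against 18485, near background at day 150, so that the size of its fall is imprecise, and Cyp3a44 was at -3.06 (SE 0.57). Of 18 fetal and imprinted genes 10 fell and 2 rose (12 and 2 when adjusted over the list alone, median -1.06, camera adjusted p = 1.3e-05, adjusted p = 0.051 with an estimated correlation). Among them were Tff3 (-5.15, SE 0.41) and Afp, alpha-fetoprotein (-2.43, SE 0.29), with Rian, an imprinted noncoding RNA, at 2.32 (SE 0.30). The amino acid response list was lower at day 150: 8 of 19 ATF4 targets and serine synthesis genes fell and 0 rose (8 when adjusted over the list alone, median -0.58, camera adjusted p = 2.9e-06, adjusted p = 0.016 with an estimated correlation). Examples were Psat1 (-4.20, SE 0.34), Asns (-1.99, SE 0.43) and Fgf21, a fasting hormone (-2.39, SE 0.48). Psat1 had signals of 35.8, 50.5 and 67.8 at day 150, near background, so that the size of its fall is imprecise.

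Fatty acid oxidation and PPAR alpha targets fell with age (16 of 32, 0 rose; 18 when adjusted over the list alone, median -0.57, camera adjusted p = 7.4e-11, adjusted p = 0.22 with an estimated correlation), with Vnn1 at -3.45 (SE 0.30) and Acot2 at -1.65 (SE 0.24). Extracellular matrix genes fell (19 of 31, 1 rose; 20 and 2 when adjusted over the list alone, median -1.04, camera adjusted p = 5.3e-10, adjusted p = 0.22 with an estimated correlation), with Sparc at -2.62 (SE 0.27) and Col4a2 at -1.34 (SE 0.20). Proteasome genes fell (14 of 31; 14 when adjusted over the list alone, median -0.27, camera adjusted p = 1.3e-05, adjusted p = 0.43 with an estimated correlation). Genes of immune cells and stress rose. Interferon response genes did (15 of 37; 21 when adjusted over the list alone, median 0.66, camera adjusted p = 3.6e-08, adjusted p = 0.32 with an estimated correlation), with Ifi47 at 1.71 (SE 0.24). Antigen presentation by MHC class II followed (4 of 7; 5 when adjusted over the list alone, median 0.85, camera adjusted p = 0.0013, adjusted p = 0.32 with an estimated correlation), with H2-Aa at 1.67 (SE 0.23), as did macrophage genes (6 of 22; 6 when adjusted over the list alone, median 0.29, camera adjusted p = 0.00094, adjusted p = 0.50 with an estimated correlation), with Mpeg1 at 1.30 (SE 0.17). Heat shock genes rose as well (8 of 16; 9 rose and 1 fell when adjusted over the list alone, median 0.40, camera adjusted p = 9.7e-05, adjusted p = 0.13 with an estimated correlation), with Hspb1 at 3.29 (SE 0.24) and Hspa1b at 1.80 (SE 0.22). In each gene named the 3 arrays of one day lay beyond the 3 of the other.

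In total 1069 genes rose and 890 fell with age, 500 of them more than 2-fold. Of all 1959 genes, 847 passed whichever of the 6 arrays was left out, the genes named here among them. The count was 1151 without control day 150 replicate 2. The day 150 arrays had a mean Gapdh 3'/5' ratio of 1.48 (SD 0.27) against 0.942 (SD 0.085) at day 21. These ratios did not overlap, with at most 0.993 at day 21 and at least 1.30 at day 150. With the 3'/5' ratios as a covariate 89 genes passed, so age and RNA integrity were not told apart. Over all list tests, the male-biased and ATF4 lists with age were the 2 camera calls that held with an estimated correlation, and none of those in the diet comparisons did.

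The test of whether a diet response differed between ages found 2 genes for each diet. After HP pregnancy these were Tmie (difference of log2 changes -4.06, SE 0.65, adjusted p = 0.035) and Rassf4 (-2.42, SE 0.35, adjusted p = 0.017). After HP lactation they were Mup3 (3.10, SE 0.42, adjusted p = 0.0060) and Mycn (4.20, SE 0.66, adjusted p = 0.027). Mup3 was lower in 3 of 3 HP lactation arrays at day 21 and at a mean signal of 17381 against 16679 in control at day 150. Slco1a1 and Bex1, which passed at day 21, had differences of 0.97 (SE 0.20) and -3.39 (SE 0.70) that did not pass (adjusted p = 0.29 for each). The Mycn call rests on control signals near background at day 150. With 50 added to the signal, Mycn did not pass (adjusted p = 0.30) and Bex1 did (-2.76, adjusted p = 0.0031), and for HP pregnancy Tmie did not pass. Mycn also missed with array weights (adjusted p = 0.10), with the compared arrays alone (0.36), without both Xist arrays (0.22) and with the 3'/5' ratios as a covariate (0.20). Tmie missed with no filter, every kept probe set, eBayes without trend, a replicate block, without both Xist arrays and with that covariate (adjusted p up to 0.28), and Rassf4 missed without trend (0.051). The stricter filter left Mycn and Tmie untested. Unadjusted p values under 0.05 numbered 426 and 562, against 550.9 by chance. Mup3 passed whichever array was left out, but not with the compared arrays alone (adjusted p = 0.10) or with the 3'/5' ratios as a covariate (0.10). Mycn missed in 9 of 12 leave-outs (adjusted p up to 0.15), Rassf4 in 4 (up to 0.071) and Tmie in 9 (up to 0.22).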

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

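In this part the tests by quantile normalization and by Xist in the HP lactation arrays were chosen after their results had been seen; the other tests of explanations were set out before.

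Results stood out here because the response to a diet differed between day 21 and day 150 in limma's test of that difference. Tmie differed by -4.06 on the log2 scale after HP pregnancy: its mean signal was 398.4 against 346.9 in control at day 21 and 13.97 against 202.9 at day 150, where its 2 probe sets not used for the test were at -2.77 (SE 0.64) and -2.41 (SE 0.64). Rassf4 differed by -2.42 after HP pregnancy, with signals of 165.3 against 92.2 at day 21 and 259.2 against 771.4 at day 150, while its 2 other probe sets differed between ages by only -0.40 (SE 1.03) and -0.99 (SE 0.51), with the opposite sign at day 21 (-0.47, SE 0.73, and -0.29, SE 0.36) and the same sign at day 150 (-0.87, SE 0.73, and -1.27, SE 0.36). Mycn differed by 4.20 after HP lactation, with 94.3 against 143.8 at day 21 and 83.0 against 6.87 at day 150, and its 2 other probe sets at day 150 were at 0.13 (SE 1.13) and 0.01 (SE 0.63). Mup3 differed by 3.10 after HP lactation, with 2676 against 22030 at day 21 and 17381 against 16679 at day 150, while its other probe set, near background at day 21, differed by -0.63 (SE 1.24). For HP pregnancy 6 of 100 drawn splits of the arrays within each day gave as many genes, with up to 7 in the others against 2, so a chance origin of the count is not excluded. For HP lactation 3 of 100 did, with up to 6 in the others against 2, a share under 0.05. The splits counted include the real one, and others gave more genes, so chance is not excluded for HP lactation either.

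The pattern weighed here is the fall of male-biased genes, Mup3 among them, with a rise of fetal and imprinted genes after HP lactation at day 21. Female RNA in the control pool with Xist signal, replicate 2, is argued against for the fetal list, whose median was 0.52 without it against 0.55 with it, while the median of -0.49 for the male-biased list decided nothing, since female RNA in control would hide a fall. Female RNA in the HP lactation pools is argued against, as their Xist signal reached at most a share of 0.0116 of that in replicate 2. The narrower signal range of the HP lactation arrays is argued against for the male-biased list, which had a median of -0.66 after quantile normalization. A younger expression state may contribute but was left undecided. Genes that rose with age in HP pregnancy offspring (283) had a median of -0.10 after HP lactation. Genes that fell (330) had one of 0.06. The difference of -0.16 ran from -0.25 to -0.0858 as single arrays were left out, where -0.1 or below had been asked of each. The mean Gapdh 3'/5' ratio was also higher at day 150 than at day 21 in HP pregnancy offspring (1.75 and 0.904). It was lower after HP lactation than in control at day 21 (0.843 and 0.942), so RNA integrity was not told apart from age here. A direct effect of the diet was not tested, nor was the time of day at sampling or a shift of the clock. After HP lactation at day 21, clock genes that peak late in the light phase or at dusk had a median of 1.09, against -0.23 for genes in antiphase.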

How the results depend on the processing

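The fits without the Xist arrays and with the 3'/5' ratios as a covariate were chosen after the data were seen, the other alternatives before. Where a cause is not given, the cause was not tested. Of 4299 values of genes, lists and covariances under an alternative, 3650 kept direction and side of the threshold, 556 lost the threshold, 87 gained it, 4 turned direction and 2 moved. The turns were Igf1 after HP pregnancy at day 21 (0.0195 after quantile normalization), the fatty acid synthesis list after HP lactation at day 21 (leave-one-out values from -0.0805, without HP lactation day 21 replicate 3, to 0.33, without control day 21 replicate 1) and the acute phase list after HP lactation at day 150 (leave-one-out values from -0.0046, without HP lactation day 150 replicate 4, to 0.23, without HP lactation day 150 replicate 6; -0.0046 also without both Xist arrays). In the order HP pregnancy and HP lactation against control at day 21, the same at day 150, HP groups against each other at day 21 and day 150, age, and the difference between ages for HP pregnancy and HP lactation, the main counts of genes were 0, 19, 290, 1, 141, 79, 1959, 2 and 2, and only counts that moved by over 1.5 times follow.

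With no filter, HP pregnancy against control at day 150 gave 146 genes, the HP groups at day 150 gave 38 and the HP pregnancy age difference 1. The stricter filter gave 130 between HP groups at day 150, 0 for HP lactation at day 150 and 1 for each age difference. With equal 75th percentiles, which moved the median of all genes by -0.12 for HP lactation at day 21, that comparison gave 36. Adding 50 to the signal gave 0 for HP lactation at day 150 and 1 for the HP pregnancy age difference, and while the HP lactation age difference kept a count of 2, Bex1 passed there in place of Mycn. Every kept probe set, a larger set of tests, gave 53 (HP lactation, day 21), 2 (HP lactation, day 150), 3056 (age), and 1 and 4 (age differences). Without trend, eBayes gave 1 (HP pregnancy, day 21), 11 (HP lactation, day 21), 72 (HP pregnancy, day 150), 54 and 16 (between HP groups) and 0 (HP pregnancy age difference). Array weights gave 1, 1053, 360, 126 and 1 (HP pregnancy at day 21 and 150, between HP groups at day 21 and 150, HP lactation age difference). An adjusted p under 0.10, a looser limit by construction, gave 1, 56, 763, 318 and 418 (HP pregnancy and HP lactation at day 21, HP pregnancy at day 150, between HP groups at day 21 and 150). The compared arrays alone, with fewer residual degrees of freedom, gave 8, 473, 0, 34, 1 and 0 (HP lactation at day 21, HP pregnancy and HP lactation at day 150, between HP groups at day 21 and 150, HP lactation age difference). Without both Xist arrays the counts were 591 (HP pregnancy, day 150), 3 (between HP groups, day 150), 1 and 1 (age differences). With the 3'/5' ratios as a covariate they were 8, 3, 84, 26, 89, 1 and 0 (HP lactation at day 21, HP pregnancy at day 150, between HP groups at day 21 and 150, age, age differences).

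The 15 arrays numbered 1 to 3 with a replicate block gave 174 genes for HP pregnancy at day 150 and 1 for its age difference. Comparisons with HP lactation at day 150, which shares no number, were not run with it. Residuals of same-numbered arrays correlated above 0.1 in 1 of 30 pairs (from -0.11 to 0.10), and 0 of 15 arrays were closest to their own number. No pairing by number was thus seen, though 3 arrays per group cannot exclude one.

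The main counts of lists were 20, 20, 20, 9 and 18 (HP pregnancy and HP lactation at day 21, the same at day 150, age). Quantile normalization gave 4, 13, 9 and 4 in the diet comparisons, with 3, 9, 9 and 3 of the original calls kept. An estimated correlation gave 0, 0, 0, 0 and 2, and fry 0, 3, 0 and 0 in the diet comparisons. Lists were not run with the stricter filter, every kept probe set, eBayes without trend, array weights, the looser limit or the compared arrays alone, and the overlap was run only with no filter, quantile normalization, 50 added to the signal and single arrays left out. Leaving out 1 array at a time gave genes from 0 to 1, 6 to 79, 2 to 162, 1 to 3, 33 to 361, 2 to 251, 1151 to 1758, 0 to 2 and 1 to 3 in the order above, and 6 to 16 lists for HP lactation at day 150, with a lone pair of arrays in a group assumed to vary like the others. The overlap r ran from 0.20 to 0.49 at day 21 and 0.34 to 0.58 at day 150. With no filter its covariance rose to 0.21 and 0.24. Depth on arrays is signal over background: at signals under the filter's 57.5, as for Mycn in control at day 150 (6.87) and Tmie after HP pregnancy at day 150 (13.97), a fold is imprecise.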

Other observations

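In this part the tests of the time of day, of the sex of the pools and of the signal range by quantile normalization were chosen after their results had been seen; the test of RNA integrity and the splits were set out before.

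Further gene groups moved on the deposited scale. After HP lactation at day 21, growth arrest genes of the p53 pathway (13 measured, 0 passed, median 0.42, camera adjusted p = 0.040, adjusted p = 0.39 with an estimated correlation) and immediate early genes (23 measured, 0 passed, median 0.25, camera adjusted p = 0.0098, adjusted p = 0.46 with an estimated correlation) were higher, and interferon response genes lower (37 measured, 0 passed, median -0.17, camera adjusted p = 0.0065, adjusted p = 0.58 with an estimated correlation). The interferon list did not pass without control day 21 replicate 1 (median -0.07, adjusted p = 0.088) or HP lactation day 21 replicate 2 (-0.10, adjusted p = 0.072). These lists passed after quantile normalization too, which also brought urea cycle (median 0.10, adjusted p = 0.014), fatty acid synthesis (0.22, adjusted p = 0.00057) and glucocorticoid and fasting genes (0.28, adjusted p = 9.5e-05) past the threshold. Phase I drug metabolism genes had a median of -0.23 and a test below 0 (adjusted p = 0.0013, adjusted p = 0.39 with an estimated correlation) but a mean of 0.01. On the deposited scale the urea cycle had a median of -0.03, a mean of 0.04 and a test below 0 that did not pass. Glucocorticoid and fasting genes thus lay on opposite sides of 0 after HP lactation (median 0.22, not past the threshold, and from 0.07 without HP lactation day 21 replicate 2 to 0.43 without replicate 3) and HP pregnancy (-0.30) at day 21; the difference between these medians was not tested.

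After HP pregnancy at day 150, female-biased genes had a median of -0.62 (22 measured, 0 passed, 17 negative, camera adjusted p = 0.033, adjusted p = 0.62 with an estimated correlation) that did not pass after quantile normalization (-0.63, adjusted p = 0.055), and antigen presentation genes of MHC class II one of -0.31 (7 measured, 0 passed, 6 negative, camera adjusted p = 0.034, adjusted p = 0.63 with an estimated correlation) that did (-0.31, adjusted p = 0.047). After HP lactation at day 150, acute phase genes had a median of 0.17 (29 measured, 0 passed) that passed after quantile normalization (0.19, adjusted p = 0.0017), and turned to -0.0046 without HP lactation day 150 replicate 4, an array with Xist signal.

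One pattern weighed is the set of 290 genes after HP pregnancy at day 150, whose arrays had a higher 3'/5' ratio (higher by 0.33 on the log2 scale). Slopes on this ratio from the day 21 arrays predicted a share of 0.105 of the median change of these genes. That share lay between -0.0062 and 0.19 as single arrays were left out. This argues against RNA integrity as the whole cause only if those slopes hold at day 150, which the test cannot show. The log2 ratios of the day 21 arrays ran from 0.36 to 0.82, and those of the 6 arrays compared here from 1.21 to 1.76. With the ratio as a covariate the median change in the original direction went from 0.63 to 0.60, while the median SE rose from 0.15 to 0.17. Then 3 genes passed, and the calls ended mainly through the wider error. The sign stayed in 290 of 290 genes, which is little evidence, since these genes were chosen for their change in the same arrays. A narrower signal range as the cause is argued against by the 307 genes that passed after quantile normalization, and female RNA in pools of 1 group by Xist, which in these 6 arrays reached at most a share of 0.0174 of the signal in the lower array with Xist signal. Open besides RNA integrity are another difference between pools, the time of day at sampling and the diet itself, since no label gives dates or sampling times. In these same arrays clock genes of opposite phase moved apart, with medians of 0.98 and -0.93, as given below. Whether the 290 genes follow the time of day was not tested.

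Another pattern is that of the clock genes at day 150, where both HP groups differed from control in opposite directions for genes that peak at opposite times. Genes that peak late in the light phase or at dusk (9 measured, Dbp and Per2 among them) had medians of 0.98 after HP pregnancy and 1.16 after HP lactation, and genes in antiphase (5 measured, Arntl and Npas2 among them) -0.93 and -0.95, differences of 1.91 and 2.11. These differences stayed between 0.99 and 2.47, and between 1.74 and 2.41, as single arrays were left out; at day 21 the same difference was 1.32 after HP lactation (from 0.69 to 1.49) and -0.37 after HP pregnancy (from -0.71 to -0.0154), seen afterwards. The differences at day 150 could come from control livers taken at another time of day than HP livers, and equally from a shift of the clock itself by either diet. No sampling time is given, and both stay open at day 150. At day 21 the HP groups moved in opposite directions against the same control arrays. This argues against a control sampled at another time than both HP groups as the sole cause at day 21. Another sampling time of the HP lactation livers, or a shift of their clock, stays open there. Both HP groups share the 3 control arrays of a day, so that their likeness at day 150 is not independent evidence.

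For groups of 3 there are 10 splits of the arrays, too few for a share under 0.05. Against control, the highest count of the other splits was 1 gene (real 0) for HP pregnancy and 1 (real 19) for HP lactation at day 21, and 2 (real 290) and 2 (real 1) at day 150; it was 68 (real 141) and 8 (real 79) between the HP groups at day 21 and 150, and 0 (real 1959) for age. Counts as large came in 10, 1, 1, 2, 1, 1 and 1 of the 10 splits, the real one included. For lists the highest others were 19 (real 20), 19 (real 20), 20 (real 20) and 21 (real 9) for HP pregnancy and HP lactation at day 21 and then at day 150, and 16 (real 18) for age, with counts as large in 1, 1, 2, 9 and 1 of 10 splits. List counts at the preset correlation thus came out nearly as high in splits that mix the groups at day 21 and for age, as high for HP pregnancy at day 150 and higher for HP lactation at day 150.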
